A study of Mus musculus with 9 samples.

How the data were processed

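Poly-A RNA of cells picked as retinal ganglion cells was measured in 9 libraries from adult male mice, 3 for each of the groups GFP, Olig2 and Olig3. Per the labels' protocols, cells were enriched on magnetic beads against CD90.2 (Thy1), GFP-positive cells were picked by hand, and complementary DNA was made with the SMART-Seq HT kit and amplified over 20 cycles. The number of picked cells differs between parts of the labels, with lower and upper limits from 10 to 20. Such a pick can carry cells other than ganglion cells or their RNA. The deposited values are whole-number counts of reads per gene in 1 table of the whole series, not normalized, with totals that differ between libraries. Reads were checked with FastQC, aligned with HISAT2 and counted with HTSeq on the mouse build mm10, as far as the tool names show, per the submitters' processing notes; versions, filters and the strand setting are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping gene on either strand cannot be told apart: Gm37376, which lies opposite Malat1 (chr19 5795690 to 5802672), had 0.941 to 1.02 times the counts of Malat1 in every library.

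The table held 50764 genes by Ensembl identifier, of which 29429 had at least 1 count and 50712 matched GENCODE release M21 of mm10, from which coordinates were taken (1-based). The 89 identifiers without a gene symbol held 0.00220 to 0.0165% of the counts and were kept, since each names a gene. Every sample column was assigned to its library by name. No pair of libraries of one group agreed within counting noise (lowest chi-square per degree of freedom 29.5), so no pair was merged, although repeat preparations of one sample would also differ by more than counting noise after amplification.

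Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test on the counts, with TMM factors, the filterByExpr filter (15609 genes tested), 1 model of group means over all 9 libraries (6 residual degrees of freedom, common dispersion 0.532) and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. The comparisons were Olig2 against GFP, Olig3 against GFP and Olig3 against Olig2. Group levels of single genes are TMM-scaled CPM as mean ± SD, and summed levels of lists and shares of counts are unscaled. Summed levels and shares were compared by two-sided exact permutation tests. A fold against a group without counts was computed against a floor of 3 counts over that group, and with 1 to 3 counts the ratio is given with its 95% counting interval, both from counts pooled over each group. Every other fold of a gene is the ratio of the group means of its CPM. The 36 gene lists, with 912 genes of which 891 are in the table, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 99 tests (33 lists with at least 5 tested genes in 3 comparisons). The list of the Olig genes and those of red blood cells and pigment epithelium had too few tested genes. The median log2 change of a list is taken over its tested members. For each member it uses the difference between groups in mean log2 CPM with a prior count of 2. That measure also gave the median of all genes and the correlation between the factors. It differs from the edgeR log2 change given for single genes and is nearer to no change for genes with few counts in a group. Members are counted after adjustment over all genes and, separately, adjusted over the list alone. Comparisons against the shared GFP libraries were set beside 40 simulations of unchanged groups.

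The groups, comparisons, tests, lists, alternative settings and the rule for named genes were fixed before the data were examined. The rule named Olig1, Olig2 and Olig3 first. It then took, per comparison and direction, the 10 genes with the smallest p (5 between the factors) among those past the threshold whose libraries did not overlap between the groups, leaving out predicted, clone and pseudogene symbols, and where none passed in a direction, the 3 with the smallest p. It further took up to 4 members of each list that passed over all genes in a comparison against GFP, or where none passed, up to 2 with the smallest p given as values, and up to 5 genes per direction that passed in both. Not every gene that the rule took from the lists is reported here. Genes named because they passed over the list alone, and those in the closing section, were chosen after their values were seen. The alternatives were other scaling factors (RLE, upper quartile, TMMwsp), leaving mitochondrial and ribosomal genes out, DESeq2 1.42.0, limma-voom with and without sample weights, robust estimation, no filter and a filter at 10 CPM in 3 libraries, fits of only the pair of groups compared, the replicate number as a block, an adjusted p of 0.1, a test against a fold of 1.5, leaving out each library, and for lists an estimated correlation and fry. Leaving out the 2 Olig3 libraries with the fewest detected genes, leaving out the 3 libraries richest in Malat1 and removing Malat1 and Gm37376 were added after seeing the data. Every fit without some libraries applied the filter anew and had fewer residual degrees of freedom. Such fits tested 16535 to 16926 genes without 1 library, 19024 without the 2 Olig3 libraries and 19056 without the 3 libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

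The test was tested on simulated data, after a first fit to the real counts, with counts drawn from the means, spread and library sizes of the real libraries in 3 simulations per comparison and 150 changed genes per fold. For Olig2 against GFP (14861 genes) it recovered 2, 22.7, 44.7 and 58% of genes changed 2-, 4-, 8- and 16-fold. For Olig3 against GFP (14930 genes) the shares were 1.33, 26.7, 48.7 and 54%, and for Olig3 against Olig2 (14883 genes) 0, 26.7, 42 and 54%. Of the genes called, 4.02, 2.97 and 6.12% were unchanged. For Olig2 against GFP (15609 genes), camera found 10 of 10 lists of 20 genes shifted 2-fold and called 2 of 320 unchanged lists. These genes were drawn independently, whereas the estimated correlation within a real list reached 0.766 (lens genes), against the preset 0.01. The 2 of 320 is thus no estimate of false calls among the real lists.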

Results

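RNA from cells picked as retinal ganglion cells, the neurons whose axons form the optic nerve, was sequenced from adult male mice 14 days after the optic nerve had been crushed. The eyes had received 1.5 µL of an adeno-associated virus coding for green fluorescent protein (GFP), Olig2 or Olig3. Olig2 and Olig3 are basic helix-loop-helix transcription factors, best known for specifying oligodendrocytes and for patterning neural progenitors. Cells were enriched on beads against the surface protein Thy1 and GFP-positive cells were picked by hand, 10 to 20 per library depending on which part of the labels is read. Each of the 3 groups (GFP, Olig2 and Olig3) held 3 libraries. The series title writes the virus as Olig1/2 while the samples are labelled Olig2 or Olig3, and the sample labels are followed here. Total counts per library ranged from 5355691 to 6979851, so 3 counts, the limit that a count of 0 allows, corresponded to 0.430 to 0.560 CPM, the count scaled to the library total. The sources used here do not state that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical. The reads were amplified over 20 cycles without molecular identifiers, so intervals and floors cover counting error only.

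Transcripts of photoreceptors were abundant in every library. The 16 rod genes held 6.66% ± 1.37 of the counts in the GFP group, 12.3% ± 3.39 in the Olig2 group and 11.4% ± 5.28 in the Olig3 group (SD, n = 3 each). Two-sided exact permutation tests gave p = 0.1 and 0.2 against GFP, where 0.1 is the smallest p that 3 against 3 libraries allow. Retinal ganglion cell markers held 0.173% ± 0.0679, 0.0563% ± 0.0133 and 0.0556% ± 0.00515 (exact permutation p = 0.1 for both factors against GFP). Genes with 10 or more counts numbered 15054 ± 123 in the GFP group, 14696 ± 298 in the Olig2 group and 12583 ± 862 in the Olig3 group (exact permutation p = 0.1 for both). Olig3 library 1, with 16188 detected genes, and Olig3 library 3, with 14434, stood apart from the others, which had 18184 to 21338. They lay at 132.8 and 176.9 on the first principal component, which carried 34.9% of the variance. Malat1, a nuclear long noncoding RNA, took 11.7% of the counts in Olig2 library 2, 6.15% in Olig2 library 3 and 8.54% in Olig3 library 2, and 2.65 to 4.14% in the other 6 libraries. The 10 most abundant genes held 38.2, 29.7 and 36.0% of the counts in those libraries, against 12.9 to 16.2% elsewhere. Correlations of log2 CPM between libraries of one group ran from 0.724 to 0.926 and between groups from 0.697 to 0.919, with medians of 0.808 within and 0.814 between groups. No pair of libraries of one group agreed within counting noise. The closest pairs by chi-square per degree of freedom lay across groups, Olig3 library 2 with Olig2 library 2 (19.2) and with Olig2 library 3 (19.4). The closest pair of one group had 29.5. Leaving out the 3 libraries richest in Malat1 keeps 1 Olig2 and 2 Olig3 libraries, and leaving out the 2 Olig3 libraries with the fewest detected genes keeps 1 Olig3 library. Both settings were chosen after seeing the data, and in both the lone library was assumed to vary like the other groups.

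**Figure D1:**
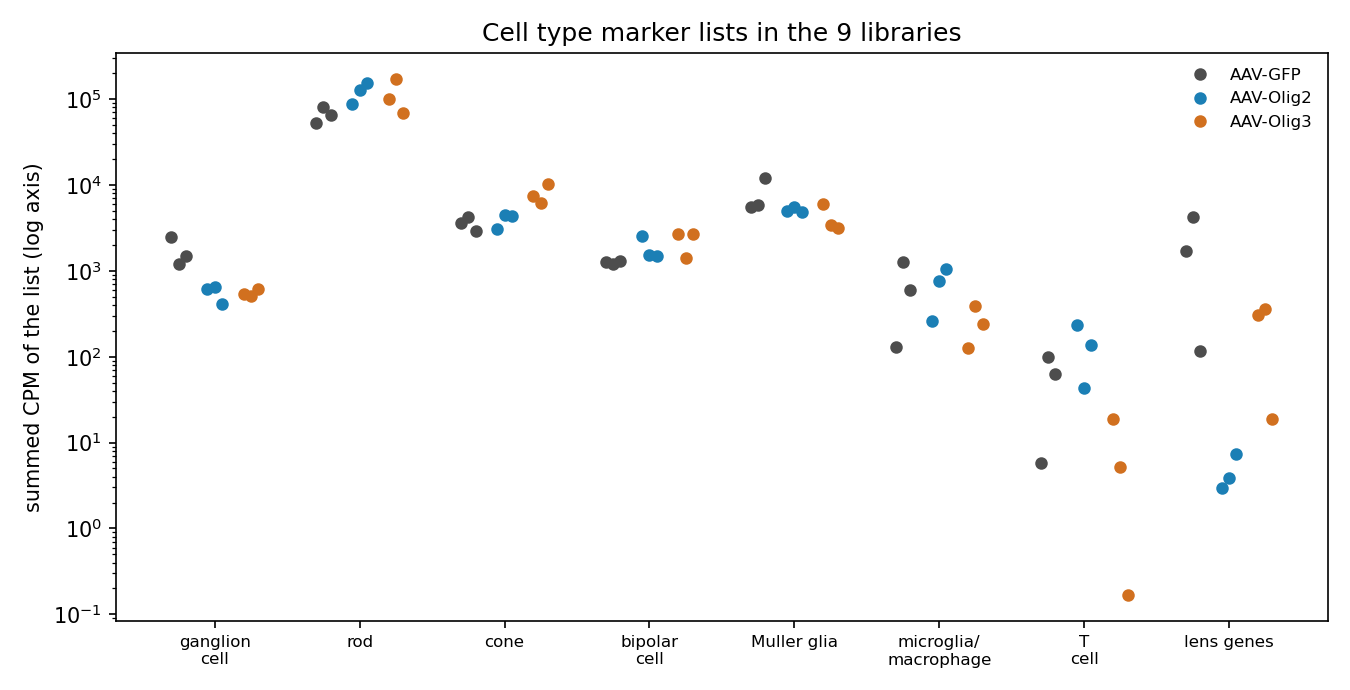
Summed CPM of 8 fixed marker lists on a log axis, with 1 point per library for the 3 GFP, 3 Olig2 and 3 Olig3 libraries. Ganglion cell markers lay at 1733 ± 679 CPM in the GFP group against 563 ± 133 and 556 ± 51.5 with Olig2 and Olig3, and lens genes at 1692, 4245.5 and 116 CPM in the 3 GFP libraries against 4.74 ± 2.33 in the Olig2 group.

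Each delivered factor was read mainly in its own group, although none of these differences passed the test. Olig2 (chr16 91225457 to 91228677) had 0 counts in the GFP libraries, 14.4 ± 9.82 CPM in the Olig2 libraries (114, 97 and 21 counts) and 0.628 ± 0.547 CPM in the Olig3 libraries. It was at least 102-fold higher with Olig2 than in the GFP group, against a floor of 3 counts over the group (edgeR quasi-likelihood log2 change 9.50, SE 2.05, Benjamini-Hochberg adjusted p = 0.375). Olig3 (chr10 19356533 to 19358604) lay at 2.43 ± 2.71 CPM in the GFP group, 0.816 ± 0.707 with Olig2 and 47.1 ± 35.1 with Olig3 (172, 113 and 597 counts), 19.3-fold above the GFP group (edgeR SE 1.31 on the log2 scale, adjusted p = 0.252). Between the factor groups, Olig2 had a log2 change of -4.50 (edgeR adjusted p = 0.918) and Olig3 of 5.88 (edgeR adjusted p = 0.618), Olig3 group over Olig2 group. Olig1 (chr16 91269772 to 91271933) had 0 or 1 count per library and was not tested. Whether the vector transcripts were counted in full at these gene models is not given in the sources used here.

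**Figure D2:**
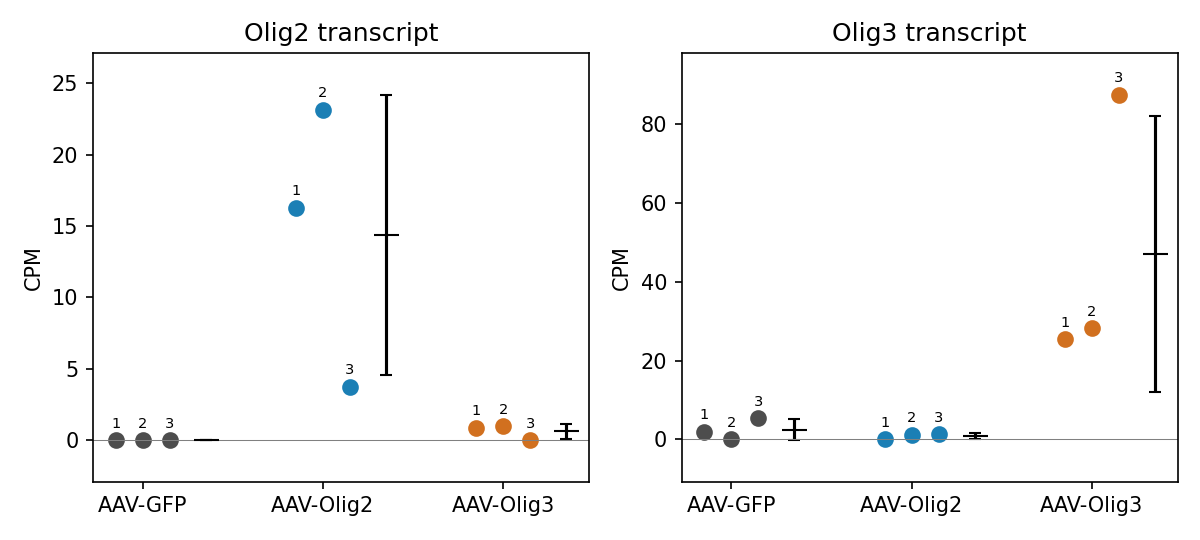
CPM of Olig2 and Olig3 transcripts in each of the 9 libraries, grouped by virus, with 1 point per library. Olig2 reached 14.4 ± 9.82 CPM in the Olig2 group and Olig3 47.1 ± 35.1 CPM in the Olig3 group.

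The first comparison asked how RNA levels differed in cells picked from eyes given Olig2 rather than GFP. Rod genes held more of the counts than ganglion cell markers in every library. A change in a marker of another cell type may thus reflect which cells were picked, which was not told apart from a change within cells. Pcp2, a G-protein modulator of rod bipolar cells, rose from 71.1 ± 7.86 to 276 ± 44.7 CPM (n = 3 per group, 3.87-fold, log2 change 1.95, SE 0.217; edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.0127). Igkc, the immunoglobulin kappa light chain constant region, rose from 8.30 ± 8.71 to 4550.4 ± 2650.1 CPM (log2 change 9.09, SE 1.10, edgeR adjusted p = 0.0127). Jchain, which joins antibody subunits, rose 14.5-fold from 14.6 ± 8.39 to 212 ± 76.5 CPM (log2 change 3.85, SE 0.449, edgeR adjusted p = 0.0127). Irf7, a transcription factor of the interferon response, fell 5.59-fold from 164 ± 15.8 to 29.4 ± 6.80 CPM (log2 change -2.49, SE 0.296, edgeR adjusted p = 0.0127). Cd63, a tetraspanin of late endosomes and exosomes, fell 4.12-fold from 581 ± 241 to 141 ± 16.7 CPM (log2 change -2.04, SE 0.287, edgeR adjusted p = 0.0311).

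The other genes past the threshold were Pet100, Slpi and Igkv14-111. Pet100, a cytochrome c oxidase assembly factor, rose from 70.0 ± 8.40 to 279 ± 54.1 CPM (edgeR adjusted p = 0.0171). Its gene model (chr8 3621548 to 3625848) contains Pcp2 (chr8 3623371 to 3625545), so the reads of the pair are not separable here. Slpi, a secreted inhibitor of leukocyte proteases, had 2 counts in the GFP group and 145 ± 123 CPM with Olig2, a ratio of 1653 (95% counting interval 457 to 13658; edgeR adjusted p = 0.0311). Igkv14-111, a kappa variable segment that resembles other segments and is uncertain for that reason, also had 2 counts in the GFP group and 324 ± 292 CPM with Olig2, a ratio of 4094 (1133 to 33815; edgeR adjusted p = 0.0456). In all, 8 of 15609 genes passed, 6 higher and 2 lower. At an unadjusted p below 0.05 there were 731, against 780 by chance. In 16.8% of genes the libraries of the pair of groups did not overlap, where chance gives 10%. The count of 8 became 0 without GFP library 1, without GFP library 3 or without Olig2 library 1. It became 5 without GFP library 2, Olig2 library 3 or Olig3 library 2, and 24 without Olig3 library 3. Igkc, Jchain and Pcp2 kept an adjusted p below 0.05 in 6 of those 9 fits and Irf7 in 5. Their highest edgeR adjusted p over them were 0.138, 0.0854, 0.0854 and 0.127. Pet100 passed in 4, Cd63 and Slpi in 3 each and Igkv14-111 in 2, with highest edgeR adjusted p of 0.165, 0.272, 0.307 and 0.357. The log2 change of Igkc was 10.43 without GFP library 2 and 8.47 without Olig2 library 1. That of Igkv14-111 (11.51 with all libraries) was 10.77 without Olig2 library 1 and 12.11 without Olig2 library 2. For Slpi (10.37 with all libraries) it was 12.78 without GFP library 2 and 9.76 without Olig2 library 1.

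Photoreceptor and bipolar cell genes were higher with Olig2 as groups, beside a rod share of counts of 12.3% against 6.66%. Rod genes had a median log2 change of 1.06. Of these, 13 of 16 rose and 0 fell when adjusted over the list alone, 0 over all genes by edgeR, and 13 lay at an unadjusted p below 0.05. The rod list had camera adjusted p = 1.01e-10, adjusted p = 0.490 with an estimated correlation, and 1.29e-12 to 0.490 over all alternatives. The sodium-calcium exchanger Slc24a1 of rods had 519 ± 86.7 CPM in the GFP group and 1028 ± 117 with Olig2, and phosducin (Pdc), which binds transducin, 2883 ± 653 and 9503 ± 3614 (edgeR adjusted p = 0.354 and 0.404). Bipolar cell genes had a median of 1.00, with 10 of 17 higher when adjusted over the list alone and 1, Pcp2, over all genes. The bipolar list had camera adjusted p = 1.38e-09, adjusted p = 0.154 with an estimated correlation, and 4.70e-11 to 0.154 over all alternatives. Cone genes had a median of 0.89, with 2 of 13, Thrb and Guca1a, higher when adjusted over the list alone, 0 over all genes by edgeR and 4 at an unadjusted p below 0.05. The cone list had camera adjusted p = 0.00178, adjusted p = 0.566 with an estimated correlation, and 7.55e-08 to 0.855 over all alternatives. The cone call was lost without GFP library 3 (median 0.62, adjusted p = 0.105) and without Olig2 library 2 (median 0.43, adjusted p = 0.0555). Without the 3 libraries richest in Malat1 the cone median turned to -0.33, with 1 Olig2 library left. The summed level of cone genes was 3592 ± 658 CPM in the GFP group and 3953 ± 801 with Olig2 (exact permutation p = 0.5). The cone median was 1.57 without Olig2 library 1.

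T cell genes and genes of the respiratory chain were higher as well, beside the rod share of counts of 12.3% against 6.66%. T cell genes had a median log2 change of 2.40, with 1 of 12, Il7r, higher when adjusted over the list alone and 0 over all genes by edgeR, while 1 lay at an unadjusted p below 0.05. The T cell list had camera adjusted p = 1.03e-08, adjusted p = 0.321 with an estimated correlation, and 1.62e-11 to 0.321 over all alternatives. Their summed level was 56.1 ± 47.2 CPM in the GFP group and 138 ± 95.2 with Olig2 (exact permutation p = 0.3). Mitochondrially encoded genes had a median of 0.74, with 0 of 12 past the threshold over the list alone or over all genes by edgeR and 5 higher at an unadjusted p below 0.05. The mitochondrially encoded list had camera adjusted p = 8.61e-05, adjusted p = 0.571 with an estimated correlation, and 2.98e-06 to 0.571 over all alternatives. Nuclear genes of oxidative phosphorylation had a median of 0.50, with 0 of 64 past either threshold by edgeR and 10 higher at an unadjusted p below 0.05. The nuclear list had camera adjusted p = 1.68e-06, adjusted p = 0.692 with an estimated correlation, and 4.93e-11 to 0.805 over all alternatives. Their summed raw level was 10977 CPM in the GFP group and 10515 with Olig2. Cytosolic ribosomal protein genes had a median of 0.28 after scaling and a raw share of counts of 0.947% in the GFP group and 0.757% with Olig2, with 0 of 78 past either threshold by edgeR and 2 higher and 1 lower at an unadjusted p below 0.05. The ribosomal list had camera adjusted p = 0.0128, adjusted p = 0.785 with an estimated correlation, and 6.32e-07 to 0.785 over all alternatives. The ribosomal call was lost without GFP library 2 (median 0.15, adjusted p = 0.547), Olig2 library 2 (0.15, adjusted p = 0.309) or Olig2 library 3 (0.17, adjusted p = 0.344). With 1 Olig2 library left, without the 3 libraries richest in Malat1, the mitochondrially encoded (median 0.35) and nuclear (0.03) calls were lost and the ribosomal median was -0.19. The T cell median was 1.55 without GFP library 1, 3.14 without GFP library 2, 3.01 without Olig2 library 2 and 3.15 without the 3 libraries richest in Malat1.

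Lens genes, regeneration-associated genes and ganglion cell markers were lower with Olig2, beside a rod share of counts of 12.3% against 6.66%. Lens genes had a median log2 change of -5.44, or -6.28 with genes at a count of 0 set to their bound. Of these, 11 of 12 fell when adjusted over the list alone and 0 over all genes by edgeR, with 11 at an unadjusted p below 0.05. The lens list had camera adjusted p = 8.66e-21, adjusted p = 0.184 with an estimated correlation, and 3.81e-31 to 0.184 over all alternatives. Cryba1, a lens crystallin, had 228 ± 235 CPM in the GFP group and 0.227 ± 0.279 with Olig2 (edgeR adjusted p = 0.180). Regeneration-associated genes, induced in neurons after axon injury, had a median of -1.32, with 2 of 34 lower when adjusted over the list alone, 0 over all genes by edgeR and 13 lower at an unadjusted p below 0.05. The regeneration list had camera adjusted p = 1.31e-11, adjusted p = 0.184 with an estimated correlation, and 5.37e-12 to 0.184 over all alternatives. The pair was Ecel1, an endopeptidase induced by nerve injury, at 24.1 ± 9.13 and 0.926 ± 0.644 CPM, and Fgf2, a growth factor, at 173 ± 55.0 and 71.7 ± 25.6 CPM (edgeR adjusted p = 0.379 and 0.451). Ganglion cell markers had a median of -1.18. Adjusted over the list alone, Tubb3, a neuronal tubulin, fell and Isl1, a transcription factor also present in bipolar and amacrine cells, rose. Over all genes 0 of 21 passed by edgeR, and 1 higher and 5 lower lay at an unadjusted p below 0.05. The ganglion cell list had camera adjusted p = 0.00165, adjusted p = 0.50 with an estimated correlation, and 0.000214 to 0.50 over all alternatives. Tubb3 had 94.3 ± 23.3 CPM in the GFP group and 41.4 ± 9.35 with Olig2, and Isl1 34.0 ± 2.46 and 72.2 ± 10.4 (edgeR adjusted p = 0.452 and 0.472). Without GFP library 1 the call of the ganglion cell markers was lost (median -0.88, adjusted p = 0.0738). The lens median was -4.46 without GFP library 2, -6.46 without GFP library 3, -4.81 without Olig2 library 1 and -7.85 with only genes at 10 CPM or more.

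Further lists were called lower with Olig2, beside a rod share of counts of 12.3% against 6.66% and a ganglion cell share of 0.0563% against 0.173%. Genes of the interferon response had a median log2 change of -0.84 with Olig2. Adjusted over the list alone, Irf7, Usp18 and Ifit1 were lower and B2m, the light chain of class I histocompatibility molecules, was higher. Over all genes 1 of 36, Irf7, was lower. The interferon list had camera adjusted p = 7.48e-06, adjusted p = 0.313 with an estimated correlation, and 1.48e-06 to 0.313 over all alternatives. Cell cycle genes had a median of -1.58, with 0 of 24 past the threshold over the list alone or over all genes by edgeR and 7 lower at an unadjusted p below 0.05. The cell cycle list had camera adjusted p = 7.48e-06, adjusted p = 0.534 with an estimated correlation, and 4.19e-14 to 0.534 over all alternatives. That call was also lost with only genes at 10 CPM or more (median -0.24, adjusted p = 0.376). Their summed level was 1828 CPM in GFP library 3 against 401 and 704 in the other GFP libraries. Integrated stress response genes had a median of -0.56. The stress response list had camera adjusted p = 0.00131, adjusted p = 0.50 with an estimated correlation, and 2.78e-05 to 0.50 over all alternatives. Axon growth cytoskeleton genes had a median of -0.21. The axon growth list had camera adjusted p = 0.00178, adjusted p = 0.559 with an estimated correlation, and 0.000366 to 0.559 over all alternatives. Adjusted over the list alone or over all genes, 0 of 25 and 0 of 40 members passed by edgeR, with 3 and 2 lower at an unadjusted p below 0.05. Without GFP library 1 the axon growth call was lost (median -0.12, adjusted p = 0.149). The cell cycle median was -2.19 without GFP library 1 and -0.33 without GFP library 3.

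The same question was asked of Olig3 against GFP, with the same limit on markers of other cell types. Of 17 bipolar cell genes, 3 passed the threshold, all of them higher. The call of the bipolar list was lost with an estimated correlation (camera adjusted p = 0.154). Grm6, the glutamate receptor of ON bipolar cells (chr11 50850685 to 50866208), rose 4.36-fold from 26.2 ± 7.36 to 114 ± 36.0 CPM (log2 change 2.12, SE 0.343). Cabp5, a calcium-binding protein of bipolar cells, rose 3.49-fold from 62.1 ± 5.51 to 217 ± 76.3 CPM (log2 change 1.80, SE 0.289), and Pcp2 2.76-fold to 196 ± 20.1 CPM (log2 change 1.46, SE 0.214). For each, with n = 3 per group, the edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p = 0.0363. Cplx3, a complexin of ribbon synapses, rose from 261 ± 53.0 to 875 ± 301 CPM and the rod exchanger Slc24a1 from 519 ± 86.7 to 1290 ± 101 CPM (edgeR adjusted p = 0.0363 for both). H2-D1, a class I histocompatibility heavy chain (chr17 35262730 to 35267499), fell 4.05-fold from 1007 ± 107 to 248 ± 59.1 CPM (log2 change -2.02, SE 0.259, edgeR adjusted p = 0.0319). Junb, a subunit of the AP-1 transcription factor, fell 4.36-fold from 243 ± 40.8 to 55.8 ± 15.6 CPM (log2 change -2.13, SE 0.275, edgeR adjusted p = 0.0319), and Fgf2, a growth factor, 4.56-fold from 173 ± 55.0 to 37.9 ± 5.29 CPM (log2 change -2.19, SE 0.335, edgeR adjusted p = 0.0363). Vim, an intermediate filament of glia, fell 7.90-fold from 347 ± 177 to 43.9 ± 21.8 CPM (log2 change -2.99, SE 0.452, edgeR adjusted p = 0.0363).

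Ip6k2, an inositol hexakisphosphate kinase (chr9 108783796 to 108806337), rose 3.20-fold from 92.4 ± 2.17 to 296 ± 57.4 CPM (log2 change 1.68, SE 0.213, edgeR adjusted p = 0.0319). Gsg1 rose 6.05-fold to 198 ± 87.6 CPM, Sphkap, an anchoring protein of protein kinase A, 3.89-fold to 260 ± 82.7 CPM (edgeR adjusted p = 0.0363 for both). Mylk, the myosin light chain kinase, rose 3.93-fold to 84.5 ± 16.3 CPM, and Pet100 to 199 ± 52.0 CPM (edgeR adjusted p = 0.0363 and 0.0372). Cd63 fell 4.10-fold to 142 ± 22.2 CPM, Irf7 3.59-fold to 45.7 ± 13.5 CPM (edgeR adjusted p = 0.0363 for both). Lrrc2 fell 4.07-fold from 569 ± 117 to 140 ± 54.8 CPM, and Ywhah, a 14-3-3 protein, 3.47-fold from 633 ± 165 to 182 ± 56.6 CPM (edgeR adjusted p = 0.0363 for both). Ecel1 fell to 0 counts, at least 140-fold lower than its 24.1 ± 9.13 CPM in the GFP group (edgeR adjusted p = 0.0363). Tgtp2, an interferon-induced GTPase, fell from 8.43 ± 6.49 CPM to 1 count, a ratio of 152 (26.9 to 6025, edgeR adjusted p = 0.0363). Its fitted log2 change (-6.80), which is no bound, was -6.03 without GFP library 3 and -8.71 without Olig3 library 1. The models of Fgf2 and Nudt6, of Junb and Prdx2, and of Tgtp2 and its near-identical paralog Tgtp1 share sequence or position, so their reads are uncertain. In all 32 genes passed, 15 higher and 17 lower, beside a median log2 change of all genes of -0.18 and fewer genes with 10 or more counts in the Olig3 libraries. At an unadjusted p below 0.05 there were 1894, against 780 by chance, and 17.2% of genes did not overlap (10% by chance). The count became 0 without any one of GFP libraries 1, 2 and 3, Olig2 libraries 1, 2 and 3 or Olig3 library 1, 2 without Olig3 library 3, and 505 without Olig3 library 2, the Olig3 library rich in Malat1. All 32 genes were among the 505. Apart from Ip6k2, which passed in 2 of those 9 fits, each gene named here passed in 1 of 9. The highest edgeR adjusted p of the named genes over these fits lay between 0.144 and 0.165. Over the same fits the log2 change was -2.12 to -1.83 for H2-D1 and -3.46 to -2.50 for Vim. The fits tested more genes with fewer residual degrees of freedom, and the Olig2 libraries enter this comparison only through the shared fit. Lost calls from these changes were not told apart from a dependence on single libraries. Without the 2 Olig3 libraries with the fewest detected genes, which leaves 1, edgeR called 0 genes, and the log2 changes of Cabp5 (1.18), Gsg1 (1.80), Sphkap (1.32) and Vim (-2.32) were smaller than with all libraries.

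**Figure D3:**
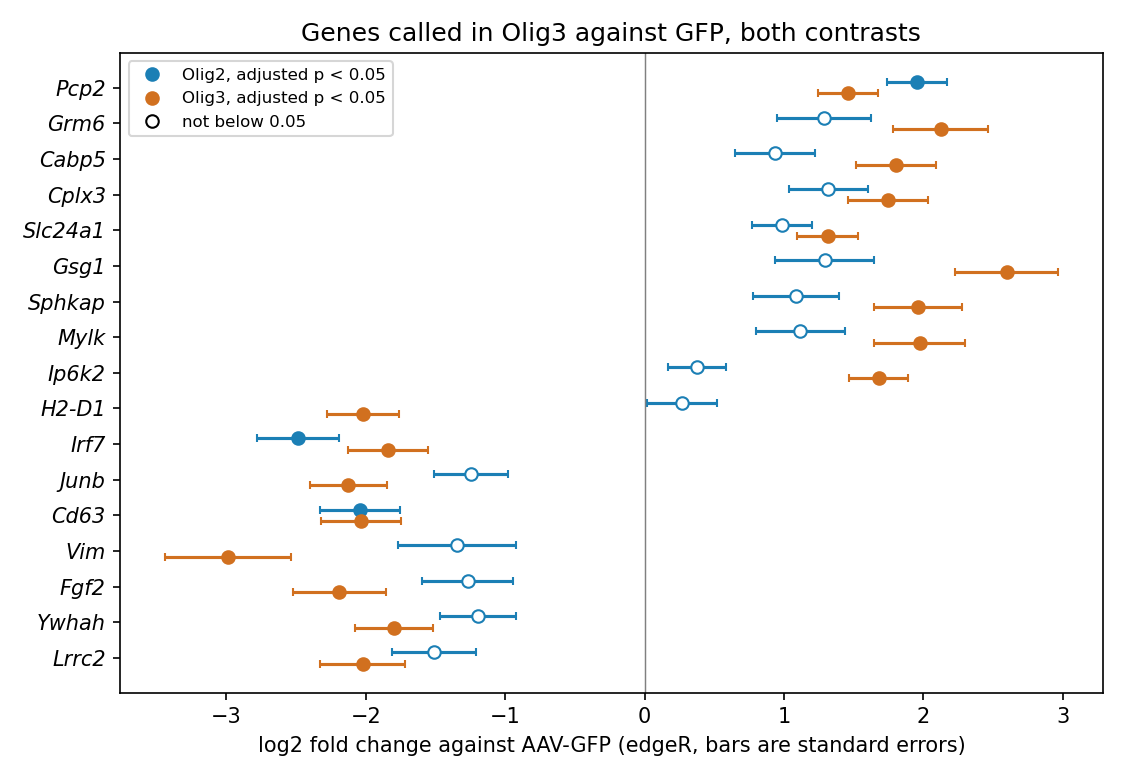
log2 fold change against the GFP group for 17 genes past the threshold with Olig3, shown for Olig2 and for Olig3, with bars of 1 standard error and filled points for an adjusted p below 0.05. Pcp2 (1.95 and 1.46) was higher and Cd63 (-2.04 in both) and Irf7 (-2.49 and -1.84) were lower past the threshold in both comparisons.

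Photoreceptor and bipolar cell genes were higher with Olig3 too, beside a rod share of counts of 11.4% against 6.66%. Cone genes had a median log2 change of 1.97, with 11 of 13 higher when adjusted over the list alone, 0 over all genes by edgeR and 11 at an unadjusted p below 0.05. The cone list had camera adjusted p = 5.55e-08, adjusted p = 0.321 with an estimated correlation, and 3.39e-10 to 0.321 over all alternatives. Arr3, cone arrestin, had 90.4 ± 54.8 CPM in the GFP group and 787 ± 347 with Olig3, and Pde6c, the cone phosphodiesterase, 39.3 ± 1.63 and 215 ± 124 (edgeR adjusted p = 0.0799 and 0.0742). The summed level of cone genes was 3592 ± 658 CPM against 7948 ± 2100 (exact permutation p = 0.1). Rod genes had a median of 1.10, with 12 of 16 higher when adjusted over the list alone and 1, Slc24a1, over all genes. The rod list had camera adjusted p = 1.35e-08, adjusted p = 0.50 with an estimated correlation, and 3.86e-16 to 0.50 over all alternatives. Bipolar cell genes had a median of 1.17, with 12 of 17 higher when adjusted over the list alone and 3, Pcp2, Cabp5 and Grm6, over all genes. The bipolar list had camera adjusted p = 1.01e-10, adjusted p = 0.154 with an estimated correlation, and 7.63e-13 to 0.154 over all alternatives. The rod median was 1.81 without the 2 Olig3 libraries with the fewest detected genes.

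4 further lists were called higher with Olig3, beside a rod share of counts of 11.4% against 6.66%. Olig3 libraries 1 and 3 had 16188 and 14434 detected genes. No member of these lists passed the threshold over the list alone or over all genes by edgeR. Chromatin and DNA methylation regulators had a median log2 change of 0.21, with 6 of 32 higher at an unadjusted p below 0.05. The chromatin list had camera adjusted p = 0.00227, adjusted p = 0.165 with an estimated correlation, and 0.00213 to 0.314 over all alternatives. Synaptic genes had a median of 0.35, with 5 of 42 higher at an unadjusted p below 0.05. The synaptic list had camera adjusted p = 0.0412, adjusted p = 0.757 with an estimated correlation, and 0.000710 to 0.757 over all alternatives. Mitochondrially encoded genes had a median of 0.52, with 3 of 12 higher at an unadjusted p below 0.05. The mitochondrially encoded list had camera adjusted p = 0.00698, adjusted p = 0.757 with an estimated correlation, and 1.09e-08 to 0.757 over all alternatives. Nuclear oxidative phosphorylation genes had a median of 0.16, with 2 of 64 higher and 1 lower at an unadjusted p below 0.05. The nuclear list had camera adjusted p = 0.00822, adjusted p = 0.785 with an estimated correlation, and 3.40e-09 to 0.785 over all alternatives. Their summed raw level was 10977 CPM in the GFP group and 10301 with Olig3. The synaptic call was lost without GFP library 3 (median 0.02, adjusted p = 0.619), Olig3 library 1 (0.36, adjusted p = 0.206) or Olig3 library 3 (0.30, adjusted p = 0.0546). It was also lost with only genes at 10 CPM or more (0.33, adjusted p = 0.0912) and with no filter on low counts (0.34, adjusted p = 0.0510). The mitochondrially encoded call was lost without GFP library 3 (0.38, adjusted p = 0.0508) or Olig3 library 2 (0.01, adjusted p = 0.264), and the nuclear call without Olig3 library 2 (-0.06, adjusted p = 0.385). Both mitochondrial calls were lost without the 3 libraries richest in Malat1 (-0.0013 for mitochondrially encoded and -0.07 for nuclear genes), and the chromatin (0.16, adjusted p = 0.314) and synaptic (0.26, adjusted p = 0.462) calls without the 2 Olig3 libraries with the fewest detected genes, which leaves 1. In that last setting the median of mitochondrially encoded genes was 1.24.

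Genes of the injury response, the interferon response and ganglion cells were lower with Olig3, beside a rod share of counts of 11.4% against 6.66% and the 16188 and 14434 detected genes of Olig3 libraries 1 and 3. Regeneration-associated genes had a median log2 change of -2.10, with 15 of 34 lower when adjusted over the list alone and 2, Fgf2 and Ecel1, over all genes. The regeneration list had camera adjusted p = 3.58e-11, adjusted p = 0.184 with an estimated correlation, and 4.94e-13 to 0.184 over all alternatives. Their summed level was 2767 ± 917 CPM in the GFP group, 827 ± 104 with Olig2 and 566 ± 70.9 with Olig3 (exact permutation p = 0.1 for both). Interferon response genes had a median of -1.72, with 14 of 36 lower when adjusted over the list alone and 2, H2-D1 and Irf7, over all genes. The interferon list had camera adjusted p = 1.01e-10, adjusted p = 0.165 with an estimated correlation, and 2.74e-15 to 0.165 over all alternatives. Ganglion cell markers had a median of -1.65, with Nefl, Stmn2, Slc17a6 and Tubb3 lower and Isl1 higher when adjusted over the list alone, 0 of 21 over all genes by edgeR, and 1 higher and 5 lower at an unadjusted p below 0.05. The ganglion cell list had camera adjusted p = 0.00206, adjusted p = 0.50 with an estimated correlation, and 0.000152 to 0.50 over all alternatives. Slc17a6, the vesicular glutamate transporter of ganglion cells, had 125 ± 7.46 CPM in the GFP group, 15.0 ± 13.2 with Olig2 and 11.7 ± 14.0 with Olig3, and Nefl, a neurofilament, 221 ± 87.8, 63.2 ± 35.6 and 54.2 ± 37.1. Axon growth cytoskeleton genes had a median of -0.73, with 1 of 40, Tubb3, lower when adjusted over the list alone, 0 over all genes by edgeR, and 1 higher and 13 lower at an unadjusted p below 0.05. The axon growth list had camera adjusted p = 0.000598, adjusted p = 0.50 with an estimated correlation, and 4.40e-06 to 0.50 over all alternatives. Gap43, a growth cone protein, had 239 ± 147 CPM in the GFP group and 9.32 ± 15.8 with Olig3 (edgeR adjusted p = 0.193). The ganglion cell median was -0.80 without Olig3 libraries 1 and 3, -2.68 without the 3 libraries richest in Malat1, -2.64 without Olig3 library 2, -1.06 without Olig3 library 3 and -2.25 with only genes at 10 CPM or more. The regeneration median was -1.26, -2.71 and -2.74 in the first 3 of these settings.

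Stress and immediate early genes were lower with Olig3 as groups, beside the same rod share and low numbers of detected genes. Integrated stress response genes had a median log2 change of -1.18, with Atf3, Asns and Nupr1 lower among 25 when adjusted over the list alone, 0 over all genes by edgeR and 7 at an unadjusted p below 0.05. The stress response list had camera adjusted p = 0.000409, adjusted p = 0.50 with an estimated correlation, and 1.16e-05 to 0.50 over all alternatives. Atf3, a transcription factor induced by axon injury, had 150 ± 57.8 CPM in the GFP group, 42.6 ± 2.26 with Olig2 and 19.9 ± 15.7 with Olig3. Immediate early and heat shock genes had a median of -0.70, with Fos, Atf3, Egr1, Zfp36, Junb and Ier2 lower among 28 when adjusted over the list alone and 1, Junb, over all genes. The immediate early list had camera adjusted p = 0.00178, adjusted p = 0.50 with an estimated correlation, and 0.000277 to 0.50 over all alternatives. Without the 2 Olig3 libraries with the fewest detected genes, which leaves 1, the immediate early call was lost (median -0.25, adjusted p = 0.0673). In the same setting the stress response median was -0.30 (camera adjusted p = 0.0130).

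Genes of Müller glia, T cells, lens and dividing cells were called lower with Olig3 as lists. The rod share and low numbers of detected genes were the same as above. Their summed levels overlapped between the GFP and Olig3 libraries. For Müller glia they were 7874 ± 3727 and 4177 ± 1599 CPM, and for lens 2018 ± 2084 and 227 ± 182 CPM (exact permutation p = 0.3 for both). For T cells they were 56.1 ± 47.2 and 8.12 ± 9.72 CPM (exact permutation p = 0.2). For dividing cells they were 978 ± 752 and 424 ± 129 CPM (exact permutation p = 0.3). Müller glia genes had a median log2 change of -1.01, with 5 of 17 lower and 1 higher when adjusted over the list alone and 1, Vim, lower over all genes. The Müller list had camera adjusted p = 0.0269, adjusted p = 0.766 with an estimated correlation, and 0.00122 to 0.766 over all alternatives. Lens genes had a median of -3.14, with 3 of 12 lower when adjusted over the list alone, 0 over all genes by edgeR and 6 at an unadjusted p below 0.05. The lens list had camera adjusted p = 8.17e-05, adjusted p = 0.571 with an estimated correlation, and 3.28e-11 to 0.571 over all alternatives. T cell genes had a median of -1.61, or -2.91 with genes at a count of 0 set to their bound, and cell cycle genes of -2.56. Adjusted over the list alone or over all genes, 0 of 12 and 0 of 24 passed by edgeR, with 9 and 9 lower at an unadjusted p below 0.05. The T cell list had camera adjusted p = 0.0161, adjusted p = 0.692 with an estimated correlation, and 2.24e-06 to 0.692 over all alternatives. The cell cycle list had camera adjusted p = 0.000634, adjusted p = 0.692 with an estimated correlation, and 2.02e-09 to 0.692 over all alternatives. The cell cycle call was lost without GFP library 3 (median -1.27, adjusted p = 0.0655) and with only genes at 10 CPM or more (-0.59, adjusted p = 0.214), and so was the lens call with only those genes (-3.46, adjusted p = 0.0528). The Müller call was lost without GFP library 3 (-0.76, adjusted p = 0.259), Olig3 library 2 (-1.30, adjusted p = 0.171) or Olig3 library 3 (-0.32, adjusted p = 0.463). The T cell call was lost without GFP library 2 (-1.10, adjusted p = 0.192), GFP library 3 (-1.42, adjusted p = 0.0943) or Olig3 library 2 (-1.66, adjusted p = 0.104). Without the 3 libraries richest in Malat1 the Müller (-1.32, adjusted p = 0.198) and T cell (-1.73, adjusted p = 0.117) calls were lost at medians no smaller than with all libraries. The lens median was -2.07 without GFP library 2, -4.21 without GFP library 3, -3.79 without Olig3 library 2, -1.69 without Olig3 library 3, -3.87 without the 3 libraries richest in Malat1 and -1.83 without the 2 Olig3 libraries with the fewest detected genes. The cell cycle median was -3.36 without GFP library 1, -3.38 without Olig3 library 2, -3.27 without the 3 libraries and -1.05 without the 2, and the T cell median -2.43 without GFP library 1.

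**Figure D4:**
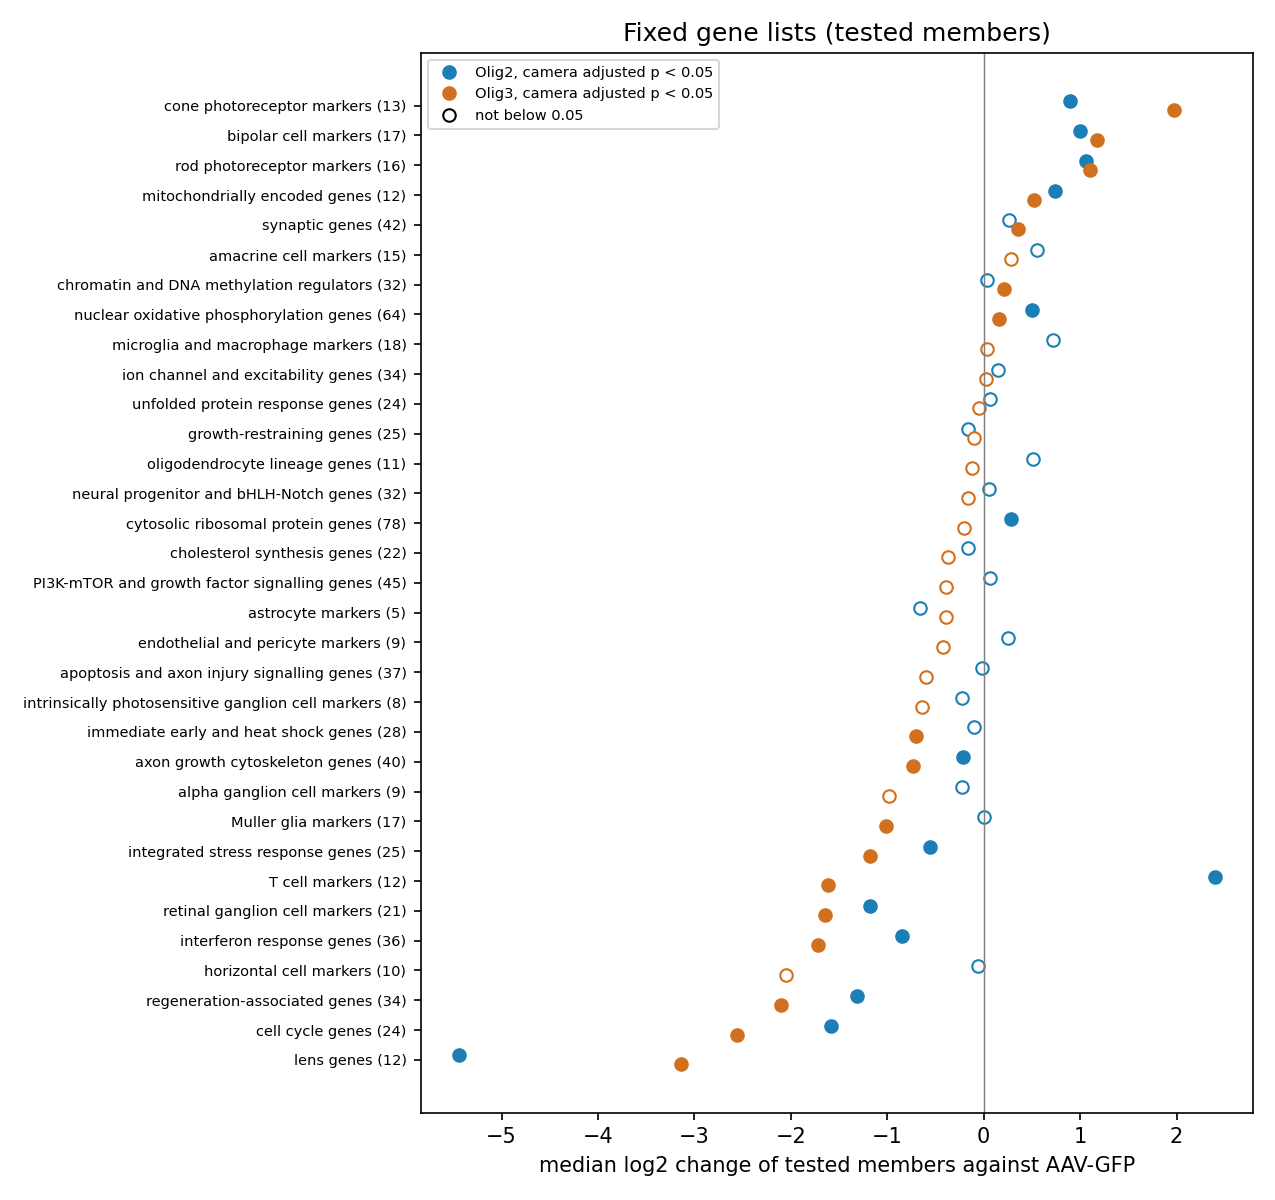
Median log2 change against the GFP group of the 33 fixed lists that could be tested, for Olig2 and for Olig3, with the number of tested members in brackets and filled points for a camera adjusted p below 0.05. Rod genes lay at 1.06 and 1.10 and regeneration-associated genes at -1.32 and -2.10, and with an estimated correlation 0 lists passed in either comparison, where the lowest adjusted p was 0.154.

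A direct comparison asked whether the 2 factors differed. H2-D1 and B2m, the heavy and light chain of a class I histocompatibility molecule, were lower with Olig3 than with Olig2. H2-D1 fell 4.88-fold from 1213 ± 269 to 248 ± 59.1 CPM (log2 change -2.29, SE 0.261, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.0132). B2m (chr2 122147686 to 122153083) fell 4.61-fold from 202 ± 47.0 to 43.8 ± 5.24 CPM (log2 change -2.21, SE 0.289, edgeR adjusted p = 0.0270; n = 3 per group). Igkc fell from 4550.4 ± 2650.1 to 3.14 ± 2.76 CPM (log2 change -10.53, SE 1.19, edgeR adjusted p = 0.0132). The interferon-induced GTPases Tgtp2 and Tgtp1, near-identical paralogs whose reads are uncertain for that reason, had 51.1 ± 22.5 and 42.5 ± 37.3 CPM with Olig2 and 1 count each with Olig3. The ratios were 945 (169 to 37365) and 829 (148 to 32767; edgeR adjusted p = 0.0132 and 0.0365). Their fitted log2 changes (-9.39 and -9.06), which are no bounds, moved to -11.31 for Tgtp2 without Olig3 library 1, and for Tgtp1 to -8.01 without Olig2 library 1 and -11.13 without Olig3 library 2. Slpi, which was chosen after its values were seen because it completes the 6 genes past the threshold, fell from 145 ± 123 CPM to 1 count (edgeR adjusted p = 0.0409).

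By edgeR 6 genes were lower and 0 were higher with Olig3 than with Olig2, against 799 at an unadjusted p below 0.05 and 780 by chance. DESeq2 called 15 higher, edgeR without the filter on low counts 23, and limma-voom 0. The genes closest to being called higher were Ip6k2 (log2 change 1.30, edgeR adjusted p = 0.0834), Plpp2, a lipid phosphatase (1.40, edgeR adjusted p = 0.527), and Pde6c (2.03, edgeR adjusted p = 0.530). In 13.1% of genes the groups did not overlap, where chance gives 10%, and the median log2 change of all genes was -0.23. The count became 2 without Olig2 library 1 or Olig3 library 3 and 160 without Olig3 library 2, and those 160 held all 6. H2-D1 and Igkc passed in all 9 fits that left out 1 library, Tgtp2 in 6, B2m in 5 and Tgtp1 in 4. Their highest edgeR adjusted p values over these fits were 0.0468, 0.0424, 0.145, 0.145 and 0.208. The count became 0 without the 2 Olig3 libraries with the fewest detected genes, and without the 3 libraries richest in Malat1 it was 8, of which 1 was among the 6. With 1 Olig3 or 1 Olig2 library left in these settings, the log2 change of H2-D1 was -2.10 (SE 0.367) and -2.13 (SE 0.344), that of B2m -2.01 (SE 0.445) and -2.60 (SE 0.443) and that of Igkc -10.05 (SE 1.46) and -11.52 (SE 1.62). Without Olig2 library 1, Olig3 library 1 or Olig3 library 3 the log2 change of Igkc was -9.93, -11.28 or -9.90.

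Of the lists, interferon response genes were lower with Olig3 than with Olig2 (median log2 change -0.97), with 8 of 36 lower and 1, Ifit1, higher when adjusted over the list alone and H2-D1 and B2m lower over all genes. The interferon list had camera adjusted p = 0.00159, adjusted p = 0.50 with an estimated correlation, and 5.58e-05 to 0.50 over all alternatives. T cell genes had a median of -4.28, or -4.97 with genes at a count of 0 set to their bound, with 11 of 12 lower when adjusted over the list alone, 0 over all genes by edgeR and 11 at an unadjusted p below 0.05. The T cell list had camera adjusted p = 1.60e-11, adjusted p = 0.217 with an estimated correlation, and 4.19e-14 to 0.217 over all alternatives. Cone genes had a median of 0.82, with Gnat2, Pde6c, Opn1sw and Arr3 higher among 13 when adjusted over the list alone, 0 over all genes by edgeR and 5 at an unadjusted p below 0.05. The cone list had camera adjusted p = 8.17e-05, adjusted p = 0.50 with an estimated correlation, and 1.16e-06 to 0.50 over all alternatives. Lens genes had a median of 2.18, or 2.68 with bounds, with 6 of 12 higher when adjusted over the list alone, 0 over all genes by edgeR and 6 at an unadjusted p below 0.05. The lens list had camera adjusted p = 2.80e-06, adjusted p = 0.50 with an estimated correlation, and 7.39e-10 to 0.50 over all alternatives. Immediate early genes had a median of -0.87, with 1 of 28, Fos, lower when adjusted over the list alone, 0 over all genes by edgeR and 8 at an unadjusted p below 0.05. The immediate early list had camera adjusted p = 0.00110, adjusted p = 0.50 with an estimated correlation, and 0.000154 to 0.50 over all alternatives. Without the 3 libraries richest in Malat1, with 1 Olig2 library left, the interferon (median -1.15) and immediate early (-0.72) calls were lost (adjusted p = 0.0644 for both), and without the 2 Olig3 libraries with the fewest detected genes the immediate early call was (median -0.10, adjusted p = 0.0677). In that setting the interferon median was -0.24 (camera adjusted p = 5.58e-05). The cone median was 0.15 without Olig2 library 1 and 2.17 without the 3 libraries richest in Malat1, where the T cell median was -5.16. The lens median was 1.42 without Olig3 library 1, 1.37 without Olig3 library 2 and 4.01 with only genes at 10 CPM or more.

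The other 4 lists called between the factors had 0 members past the threshold over the list alone or over all genes by edgeR. Chromatin regulators had a median log2 change of 0.21, with 2 of 32 higher at an unadjusted p below 0.05. The chromatin list had camera adjusted p = 0.000610, adjusted p = 0.154 with an estimated correlation, and 0.000277 to 0.154 over all alternatives. Ribosomal protein genes had a median of -0.47, with 2 of 78 lower at an unadjusted p below 0.05. The ribosomal list had camera adjusted p = 0.000719, adjusted p = 0.781 with an estimated correlation, and 4.74e-08 to 0.923 over all alternatives. Regeneration-associated genes had a median of -1.09, with 3 of 34 lower at an unadjusted p below 0.05. The regeneration list had camera adjusted p = 0.00412, adjusted p = 0.566 with an estimated correlation, and 0.000517 to 0.566 over all alternatives. Bipolar cell genes were called higher although their median was -0.02 and their mean 0.18, with 4 of 17 higher and 1 lower at an unadjusted p below 0.05. The bipolar list had camera adjusted p = 0.0159, adjusted p = 0.50 with an estimated correlation, and 0.00149 to 0.929 over all alternatives. The regeneration call was lost without Olig2 library 2 (-0.87, adjusted p = 0.0699) and the ribosomal call without Olig2 library 3 (-0.38, adjusted p = 0.0750). The bipolar call was lost without Olig2 library 2 (-0.04, adjusted p = 0.0623), Olig2 library 3 (0.05, adjusted p = 0.0669), Olig3 library 1 (0.02, adjusted p = 0.191) or Olig3 library 3 (0.26, adjusted p = 0.0553), and with only genes at 10 CPM or more (-0.03, adjusted p = 0.0657). Without the 2 Olig3 libraries with the fewest detected genes the regeneration (-0.20, adjusted p = 0.508), ribosomal, bipolar and chromatin (0.15, adjusted p = 0.118) calls were lost. Without the 3 libraries richest in Malat1 the first 3 of these were lost, at medians of -0.84, -0.21 and -0.10. Each of these settings leaves 1 library in one of the groups. The regeneration median was -1.90 without Olig3 library 2.

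Pcp2 and the overlapping Pet100 rose, and Cd63 and Irf7 fell, past the threshold with both factors against GFP. Since the reads of Pcp2 and Pet100 are not separable, these are 1 higher signal and 2 lower genes. In 40 simulations of unchanged groups that shared simulated GFP libraries the mean was 0.025 genes higher and 0 lower. For independent lists, with Pcp2 and Pet100 counted as 2 genes, the expected overlap was 0.00577 and 0.00218. The simulations held no changed genes, and the independent lists leave out the shared GFP libraries. Neither value therefore tells whether spread in those shared libraries produced the overlap. By edgeR 0 genes passed in opposite directions. Across genes, which are not independent replicates, the log2 changes of the factors correlated at r = 0.509, where the simulations gave 0.495 (0.480 to 0.510), and 67.5% of genes had the same sign, where they gave 66.5%. The covariance was 0.573 against a simulated 0.416, a difference of 0.157. Since the 3 GFP libraries cannot be split into parts of at least 2 libraries, part of the excess may come from the shared controls.

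The remaining lists were not called in any of the 3 comparisons by camera, which tests a shift in one direction. They were the markers of alpha and of intrinsically photosensitive ganglion cells, astrocytes, microglia and macrophages, amacrine cells, horizontal cells, and endothelial cells and pericytes. The others were the genes of the oligodendrocyte lineage, of neural progenitors and Notch signalling, of growth restraint, of apoptosis and axon injury signalling, of PI3K-mTOR signalling, of ion channels, of the unfolded protein response and of cholesterol synthesis. Ptprz1, a phosphatase of oligodendrocyte precursors and glia, had 47.6 ± 26.3 CPM in the GFP group and 156 ± 87.3 with Olig3 (log2 change 1.72, edgeR adjusted p = 0.266). Map3k12, a kinase of axon injury signalling, had 160 ± 11.4, 286 ± 44.5 and 311 ± 23.8 CPM in the GFP, Olig2 and Olig3 groups. Of 37 apoptosis and axon injury genes with Olig3 against GFP, 3 rose and 2 fell when adjusted over the list alone. Of these, 1, Ecel1, was lower over all genes. When fry asked for changes in either direction, that list had adjusted p = 0.00172 with Olig2 and 8.45e-05 with Olig3. With Olig3 it gave adjusted p = 0.00509 for growth restraint, 0.0157 for neural progenitors and 0.0234 for PI3K-mTOR genes. The median and the direction given by camera differed in sign for 6, 3 and 8 of the 33 lists in the 3 comparisons, and among called lists only for the bipolar genes between the factors.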

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

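The tests of the immunoglobulin pattern were chosen after its values were seen, and those of other splits of the libraries were planned.

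The difference between Olig3 and Olig2, tested directly by edgeR, passed the threshold for 6 genes, with log2 changes of -10.86 for Slpi, -2.21 for B2m, -2.29 for H2-D1, -10.53 for Igkc, -9.39 for Tgtp2 and -9.06 for Tgtp1. Against GFP, the log2 changes with Olig2 and Olig3 were 0.27 and -2.02 for H2-D1, 0.94 and -1.26 for B2m, 2.59 and -6.80 for Tgtp2, 1.48 and -7.57 for Tgtp1, 9.09 and -1.45 for Igkc and 10.37 and -0.49 for Slpi, where the values of Slpi and those of Tgtp2 and Tgtp1 with Olig3 rest on 1 or 2 counts in a group and are no bounds. Of the 10 splits of the 6 libraries into 3 and 3, 2 called at least 6 genes, the real one and the split of Olig2 library 1 with Olig3 libraries 1 and 3 against the others, which called 13. That split separates the 3 libraries richest in Malat1 from the rest and points to a structure of the samples. Its other side holds Olig3 libraries 1 and 3, with the fewest detected genes (16188 and 14434), so the split cannot tell the 2 features apart. Without the 3 libraries richest in Malat1, 1 Olig2 library is left, assumed to vary like the other groups. H2-D1 then had a log2 change of -2.13, B2m of -2.60 and Igkc of -11.52. Without the 2 Olig3 libraries, which leaves 1, these were -2.01 for B2m, -2.10 for H2-D1 and -10.05 for Igkc. The values in these settings do not show that the differences come from that structure. For Olig2 against GFP 1 of 10 splits called as many as the real 8 (highest other 0), and for Olig3 against GFP 1 of 10 called as many as the real 32 (highest other 0); 10 splits are too few for a share under 0.05.

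The immunoglobulin transcript Igkc was high in all 3 Olig2 libraries, at 7575 CPM, 2637 CPM and 3439 CPM, against 0 to 18.3 CPM in the other 6. Ighg1 was high in Olig2 libraries 1 and 3 (15501 and 5303 CPM) but at 18.1 CPM in Olig2 library 2. Index cross-talk from 1 library into the others would keep the genes in 1 ratio. Ighg1 per Igkc read was 2.05, 0.00687 and 1.54 in the Olig2 libraries, a 298-fold range. The range argues against cross-talk as the source of the Igkc reads in Olig2 library 2. It does not address transfer between Olig2 libraries 1 and 3, whose ratios lay close. Plasma cells or their RNA among the picked cells stay open. Bead enrichment and picking by GFP did not keep out other RNA, since rod genes held 5.33 to 17.2% of the counts in the libraries. The median of non-immunoglobulin plasma cell genes lay at percentile 100 of 10000 matched random lists, but at 96.12 without Mzb1 and Jchain. Both had already been seen to be high, so the test was revised after its first result. Among the plasma cell genes Xbp1 was at 92.8 to 203 CPM in every library. Mzb1 was at 51.4, 25.3 and 14.5 CPM in the Olig2 libraries and at most 0.250 CPM elsewhere. An effect of Olig2 itself was not tested and cannot be told apart from such material, which may differ between picks for reasons the labels do not give.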

How the results depend on the processing

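The settings that leave out libraries rich in Malat1 or poor in detected genes were chosen after seeing the data. Over all alternatives, named genes stayed on their side of the threshold in 3526 values, of which 3029 were of genes without a call. Values of called genes kept the call in 497 and lost it in 359. A call was gained in 145 values. The sign was not kept in 8 of the 3526, all of genes without a call, and in 0 of the others. Lists stayed on their side in 1897 values, 705 of them of called lists. The median did not keep its sign in 106 of the 1897 (4 of them of called lists). Lists lost the call in 126 values (sign of the median not kept in 7) and gained one in 36 (4). In 5 further values camera gave the opposite direction with a call as reported or under the alternative. Genes called for Olig2 against GFP, Olig3 against GFP and Olig3 against Olig2 (8, 32 and 6 as reported) were 116, 637 and 105 with DESeq2 and 176, 556 and 140 with no filter on low counts, and both held all reported genes. They were 6, 78 and 1 with limma-voom, 85, 7 and 1 with sample weights, 23, 0 and 2 with only the pair of groups in the fit, 11, 87 and 12 at an adjusted p of 0.1, and 5, 0 and 4 when tested against a fold of 1.5. RLE, upper-quartile and TMMwsp factors gave 8, 27 to 34 and 6. With the replicate block they were 10, 0 and 8, and the list calls of synaptic genes (adjusted p = 0.0536) and Müller glia (adjusted p = 0.0642) for Olig3 against GFP were lost, but the replicate numbers did not pair the libraries, whose deviations correlated at -0.0634 to 0.113 over 9 same-numbered pairs. Leaving out each library in turn gave 0 to 24, 0 to 505 and 2 to 160. Without the 2 Olig3 libraries with the fewest detected genes the counts were 41, 0 and 0, and without the 3 libraries richest in Malat1 5, 20 and 8, where the lone Olig3 or Olig2 library left was assumed to vary like the other groups. Lists called (14, 17 and 9) were 0, 0 and 0 with an estimated correlation and 4 between the factors without the 3 libraries richest in Malat1. By fry, which asks whether a list moves one way and not whether it differs from other genes, 1, 5 and 3 lists passed, of which PI3K-mTOR genes for Olig3 against GFP and against Olig2 were not called by camera. When fry asked for changes in either direction, 6, 14 and 3 lists passed. Without the 2 Olig3 libraries the median of nuclear oxidative phosphorylation genes between the factors turned to 0.22 and that of mitochondrially encoded genes to 0.36, without the 3 libraries the medians of cone (-0.33) and ribosomal (-0.19) genes for Olig2 turned, and leaving out 1 library moved the horizontal cell median for Olig2 between -1.44 (without GFP replicate 3, where camera's direction turned) and 0.79. The correlation of fold changes was 0.414 to 0.597, and the median correlation of libraries within groups 0.869 by Spearman (0.808 as reported). Fitted changes of Slpi, Igkv14-111, Tgtp1, Tgtp2 and Ecel1, which rest on 0 to 2 counts in one of the groups, moved by over 1.5 times under several alternatives. For each of these changes the cause was not tested. Settings for normalized values were not run because the values are counts. Depth limits genes without reads to 0.430 to 0.560 CPM per library.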

Other observations

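The tests on matched lists, gaps between lists, unequal falls and crystallin shares, and the use of camera to weigh a random loss of genes, were chosen after the patterns were seen, and the genes below that no list holds were chosen after their values were seen.

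Among 24 plasma cell genes other than immunoglobulins, 3 had reads in the 3 Olig2 libraries and 0 counts in the other 6. Cd79a, a component of the B cell receptor, lay at 9.99, 8.58 and 13.1 CPM in the Olig2 libraries, Cd79b at 5.56, 4.29 and 5.2 CPM and the B cell coactivator Pou2af1 at 3.85, 2.38 and 4.84 CPM. Other members differed from this: Sdc1 had 18, 7 and 0 counts in the GFP libraries against 1, 1 and 0 with Olig2, Eaf2 22, 34 and 9 against 7, 4 and 12, and Cd38 53 counts in Olig3 library 1 against 2, 25 and 41 with Olig2. Irf4 had 18, 3 and 1 counts in the GFP libraries against 3, 11 and 0 with Olig2, and Tnfrsf17 had 0 counts in every library. How many of all genes share the pattern of the 3 was not determined. Ighg1, a heavy chain constant region, was at 15501 CPM, 18.1 CPM and 5303 CPM in the Olig2 libraries and at 9.0 CPM or less elsewhere. Prdm1, a transcription factor of plasma cells and of photoreceptor precursors, was at 62.5, 7.75 and 18.6 CPM in the Olig3 libraries and at 14.4 CPM or less in the other 6.

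Cd74, the invariant chain of class II histocompatibility molecules, which present antigen on macrophages and B cells, had 5.01, 2.25 and 0 CPM with Olig3 against 121 to 510 CPM with Olig2 and 25.4 to 328 CPM in the GFP group (log2 change -6.20 for Olig3 against GFP, edgeR adjusted p = 0.0591). H2-Ab1, a class II chain, had 11.8, 4.0 and 0 CPM with Olig3, 60.8, 599 and 480 CPM with Olig2, and 15.4, 626 and 277 CPM in the GFP group. Of the genes that load class I molecules, the peptide transporter Tap1 had 9.88, 1.75 and 0 CPM with Olig3 against 29.6 to 34.1 CPM with Olig2 and 39.5 to 48.0 CPM in the GFP group, and the immunoproteasome subunit Psmb8 0.147, 21.0 and 7.04 CPM against 86.3 to 96.6 CPM and 74.6 to 99.5 CPM. Tap2 had 0, 9.75 and 7.63 CPM with Olig3 against 8.79 to 38.2 CPM with Olig2, which overlap. Tapbp had 96.4, 66.0 and 23.2 CPM with Olig3 against 44.9 to 64.1 CPM with Olig2 and 147 to 176 CPM in the GFP group.

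Ganglion cell markers were lower in the Olig2 and Olig3 libraries than in the GFP libraries, and 3 tested explanations cannot be told apart here. Random loss of low-abundance genes in less complete libraries stays open. The list's median lay at percentile 0 and 0.02 of 10000 lists matched on expression, but such lists ignore that members move together. Camera with an estimated correlation gave adjusted p = 0.50 for both factors. With only genes at 10 CPM or more the Olig3 median was -2.25, no smaller than the -1.65 of all tested members. Detected genes numbered 20080 ± 1671 in the Olig2 group and 18643 ± 204 in the GFP group (exact permutation p = 0.4). Olig2 library 1 had 18184, fewer than the 18425 to 18830 of the GFP libraries. The Olig2 libraries had fewer genes with 10 or more counts (14696 ± 298 against 15054 ± 123, exact permutation p = 0.1). Fewer ganglion cells, with every other cell type diluted less, would raise the lists of 6 other cell types alike. Rod and astrocyte genes (1.11 and -0.91 with Olig2) and cone and astrocyte genes (1.83 and -1.51 with Olig3) were 5.91 and 4.02 standard errors apart, where the largest of 15 gaps needs 4.74; without the astrocyte list, which had 5 tested genes and a summed level of 1015, 1029 and 1137 CPM in the GFP, Olig2 and Olig3 groups, the gaps were 2.79 and 2.70, so this stays open too. A lower RNA level within ganglion cells under the factors would let members fall unequally, and they did (Cochran's Q over n = 21 genes, chi-square approximation, larger p = 3.19e-07, with standard errors from 3 libraries per group and genes that are not independent), but unequal falls also arise when other cells express some members, a reading adopted after the result was seen.

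Lens genes lay at 1692, 4245.5 and 116 CPM in the GFP libraries, at 307, 355 and 18.8 CPM in the Olig3 libraries and at 2.96 to 7.38 CPM in the Olig2 libraries. Lens fibre material carried into the picks is a candidate source and stays open. Enrichment and picking did not keep out other RNA, as the rod share of 5.33 to 17.2% of the counts shows. The 6 tested lens genes other than crystallins had a median log2 change of -0.24 for Olig2 against GFP, at percentile 12.39 of matched random lists. However, 4 of them (Tdrd7, Caprin2, Cap2 and Maf) had reads in at least 8 libraries, which can hide a small share. Of the others, Bfsp2 had 38, 344 and 21 counts in the GFP libraries against 0, 8 and 15 with Olig2, and of those not tested Grifin had 47, 97 and 0 against 0, 0 and 0, Lgsn 40, 77 and 0 against 0, 0 and 4, and Mip 11, 55 and 0 against 0, 0 and 9. If all libraries drew on 1 crystallin source, Cryaa would keep 1 share of crystallin reads; over the 5 libraries with at least 500 such reads its highest share was 2.28 times the lowest without Cryab, which retinal glia also make, and 5.31 times with it, while Olig3 library 3, under that minimum, had 0 Cryaa reads among 111 without Cryab (up to 3.27%) against 21.9 to 49.9% in the 5, although 1 library with few reads leaves this open, and the version without Cryab was adopted after the first result was seen. An effect of the factors was not tested separately, and no value here separates it from such material, so these explanations cannot be told apart.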
